A study of Homo sapiens with 2 samples.

How the data were processed

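Total RNA of HCT116 cells was labelled with Cy3 (Agilent Quick Amp kit) and hybridised to Agilent single-colour arrays, per the labels' protocols, with 1 array for miR-204-5p mimic transfection and 1 for the negative control, each at 48 h. Signals were extracted with Agilent Feature Extraction 9.1, per the submitters' processing notes. The array platform's name, the genome build of the probe coordinates and the authors' normalization method are not given in the sources used here.

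The deposited scanner files hold a linear intensity for each of 44495 spots per array, not normalized between arrays. Their values have no negatives and reach down to a smooth floor, so they were read as background-corrected processed signal, which no header states. The authors' deposited table holds 20291 probes with a raw intensity, a log2 normalized intensity and a linear fold (ratio of mimic to control) for each, per the file headers. The header limits it to probes flagged as detected in 5 of 5 samples, of which 3 are not analysed here. The deposited series value table equals those log2 normalized values to within 0.005, with medians of 9.81 on the mimic array and 9.21 on the control array, so its scale is log2, its rows are not centred and its direction is that of the labels.

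The deposited values were examined before use. Of the 44493 mimic spots with a value (2 had none), 42509 (95.5%) were 1.2 times a number of 7 significant digits, which holds for 18.0% of the control array's spots, while 100% of the control array's spots had 7 significant digits as they stood. The pattern covered 100% of the 1377 spike-in, corner and negative-control spots. A factor of 1.2 for a whole array is a log2 shift of 0.26 and is removed by scaling. Of the 1359 probes with a spot off this pattern, 1357 were marked Down in the authors' deposited table. In that table the raw mimic intensity of 1366 of the 1367 Down probes equalled the control intensity times the deposited fold within a relative tolerance of 1e-06, which held for 0 of the 18924 Up probes. The scanner file carries the same numbers: the mimic intensity there equalled the table's raw intensity, within the same tolerance, for 1293 of 1293 Down probes with a single spot. Probes with that equality in the table are named recomputed here. Of the 74 Down probes with at least 8 spots, whose spots were averaged here, the median of the mimic spots equalled the table's raw intensity for 66, and 67 had every mimic spot off the 1.2 pattern. At 7 of them, named after their values were seen, some spots were on it, 9 of 10 at ZNF586, RND3, HPS3 and IL6 and 1 of 10 at GSTA4, GSTM1 and ZNF485. After 0.6 was taken off, 90.8% of the log2 normalized mimic values of Up probes fell on a value of the control column within 2e-06, against at most 0.98% at any other of 401 shifts between -2.0 and 2.0.

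Log2 intensities of the spots of a probe were averaged, and each array's 75th percentile over its 34127 non-control probes was subtracted. Values printed as intensities were scaled back by the geometric mean of both percentiles. No flag per array was in the files used, so detection was membership in the authors' deposited table, and genes detected on a single array could not be listed by the planned rule. Probes were named through their Entrez identifier (17578 probes), through an accession (130) or by the file's own symbol (676), with symbols from RefSeq on GRCh38.p14, and 1907 table probes stayed without a name. A gene's value was the mean over its table probes. Levels of Y-linked genes and XIST are not listed, and some genes that the rule would name are not reported here.

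With 1 array per group there is no test, p-value or SE. Genes were counted at 2-fold, members of lists at 1.5-fold. For each of 23 gene lists, the median difference was placed among 10000 random lists of the same size drawn within 20 bins of mean intensity, as a description of these arrays, and a list was said to stand apart below percentile 2.5 or above percentile 97.5. The groups, lists, thresholds and the rule for named genes were fixed before the data were examined. The list of reported targets was written from memory, so each entry's evidence was not checked. Named genes were RAB22A and the reported targets at least 1.5-fold different, at most 12, largest first; the 10 largest differences each way among genes above the median intensity whose probes all had 1 direction; and the 4 members of each list with the largest absolute difference. The planned comparison of genes with miR-204-5p seed sites was not run, since no 3' UTR sequence was used here.

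Alternatives were quantile and cyclic loess normalization and normexp with an offset of 50 (limma 3.58.1 in R 4.3.3), the deposited normalized values, a constant of 32 added after scaling, no detection filter, the brighter part of the detected probes, the brightest probe per gene, and thresholds of 1.5-fold and 3-fold. Chosen after the data were examined were the deposited values less 0.6 on the mimic array, the results without recomputed probes, and scaling on the median of the table's probes. The 320 E1A spike-in spots had a median intensity of 6.32 on the mimic array and 4.02 on the control array, near that of the negative controls, and were not used for scaling. Some E1A probes lay above the floor, the brightest at log2 5.56 and 5.44, a difference of 0.12 before scaling. Other steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

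The steps were tested on simulated data, a second array made from the control array's values with a shift, spot noise with an SD of 0.064 log2 and 200 changed genes among 14933. All 50 genes at a true 4-fold and all 50 at a true 3-fold were counted at 2-fold, as were 0 of 50 at 1.4-fold, 0 of 50 at 1.2-fold and 0 of 14703 unchanged genes. Noise of that size is far below a 2-fold difference, so these counts were near certain beforehand and check the arithmetic only. They do not give the rate of false calls, since differences between cultures were not simulated and the real gap between 2 probes of a gene had a median of 0.48. A list of 30 genes shifted by 0.5 came out at 0.49 and percentile 100, and 194 of 200 unshifted lists lay inside the central 95%.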

Results

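Gene expression was measured in cells labelled HCT116, a human colorectal carcinoma cell line of epithelial origin, 48 h after transfection with a synthetic mimic of the microRNA miR-204-5p or with a negative control RNA. Whether both arrays hold this line stays open, as set out in the last paragraph, so a difference between them need not be an effect of the mimic. Each condition had 1 single-colour Agilent array, so there were 2 arrays in all and no replicates. Every difference therefore describes these 2 arrays, carries no replicate error and was not tested. The arrays held 34127 distinct non-control probes, of which 20291, standing for 14933 named genes, were in the authors' table of detected probes. The 75th percentile of probe intensity was 1364 on the mimic array and 894 on the control array, against median negative-control intensities of 5.59 and 3.60. Differences are given as log2 intensity, mimic minus control, after each array was scaled to its 75th percentile, and intensities are on that scaled scale. As a guide to technical spread, the mimic-minus-control log2 difference was taken at each spot. Its SD over the spots of a probe had a median of 0.064 over 788 probes with at least 8 spots. The median gap between the probes of the 2545 genes with 2 probes was 0.48.

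The first comparison asked which transcripts differed between mimic-transfected and control-transfected cells. Among genes above the median intensity whose probes all had 1 direction, those furthest above the control were S100A14, a calcium-binding protein of epithelia, with an intensity of 17203 against 41.5, and GAL, which encodes the neuropeptide galanin, with 49235 against 178. IGFBP2, a binding protein for insulin-like growth factors, was 257-fold higher, and ALDH1A3, a retinaldehyde dehydrogenase, was 166-fold higher. Those furthest below the control were GNG11, a G protein gamma subunit, with 26.3 against 33831, and MAGEC1, a cancer-testis antigen, with 41.5 against 17346. NR3C1, the glucocorticoid receptor, was 161-fold lower. Also among the 10 largest differences each way in that set were GJC1, NTSR1, CRIP1, EPCAM, FBXO2 and GRIN2D on the higher side, between 76.6-fold (GRIN2D) and 190-fold (GJC1), and S100P, CYP1B1, ARHGDIB, GSTM3, AMIGO2 and PLAC8 on the lower side, between 144-fold (PLAC8) and 299-fold (S100P). The file's coordinates place the only PLAC8 probe on chromosome 12, and whether it reads PLAC8 itself was not checked.

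Of 14933 genes, 2082 were at least 2-fold higher on the mimic array and 2134 were at least 2-fold lower, so that 49.4% of the genes past the threshold were higher. With the authors' deposited normalized values the same threshold gave 4616 higher and 1022 lower genes, of which 81.9% were higher, because the median of all genes lay at 0.58 log2 there and at -0.05 in the scaling used here. The middle 50% of genes lay between -0.58 and 0.54, and the extremes were -10.33 and 8.70. For 1366 probes the deposited raw mimic signal was the control signal multiplied by the fold in the authors' deposited table, within a relative tolerance of 1e-06, and these are named recomputed probes here. The scaling used here takes a further 0.61 log2 off the ratio, so VIM, from such a probe, is 128-fold lower here and 83.6-fold lower by the deposited fold. At least 1 recomputed probe stood behind 1139 of the 2134 lower genes (53.4%) and behind 681 of the 682 genes that were at least 4-fold lower, among them each of the lower genes named above, whereas the 10 higher genes rested on none.

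**Figure D1:**
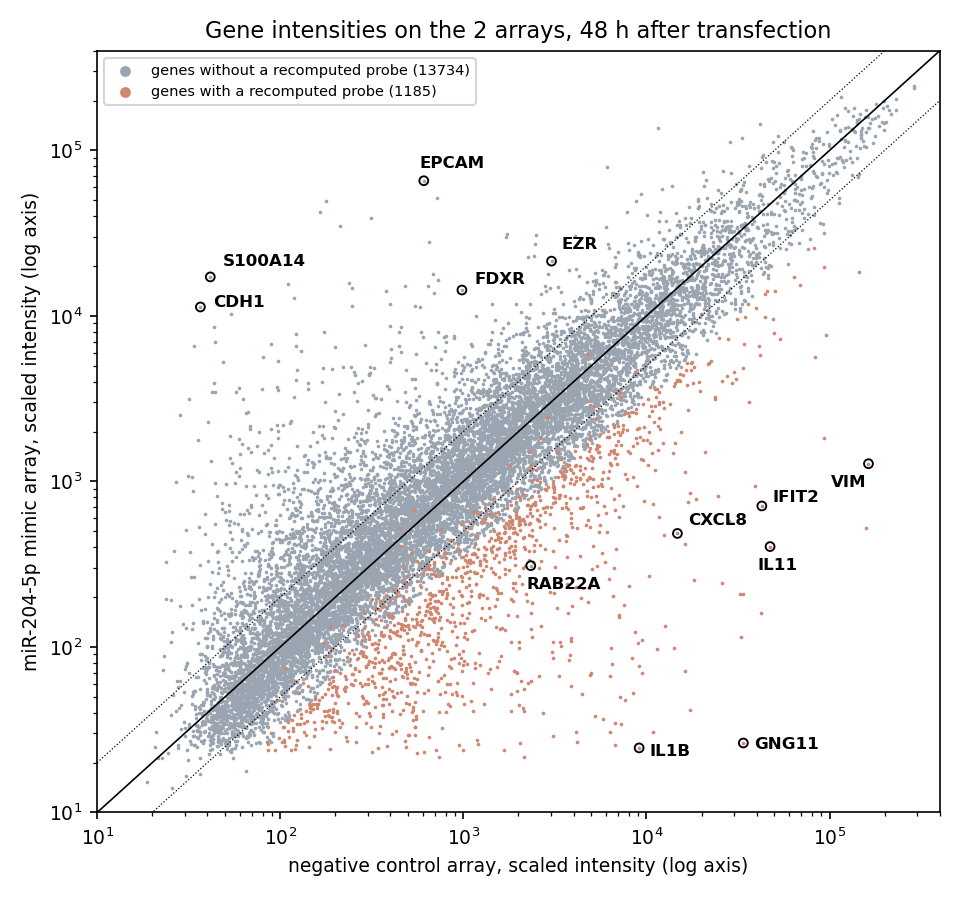
Scaled intensity of each gene on the mimic array (vertical, log axis) against the control array (horizontal, log axis), 1 point per gene, with orange for genes that have a recomputed probe, the solid line for equal intensity and dotted lines for a difference of 2-fold. CDH1 (11324 against 36.6) and EPCAM (65569 against 608) lie far above the line, and VIM (1279 against 163211) and GNG11 (26.3 against 33831) far below it.

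RAB22A, a small GTPase of early endosomes and a reported target of miR-204-5p, came first among the genes examined for the microRNA itself. Its scaled intensity was 310 on the mimic array and 2334 on the control array, a log2 difference of -2.91 or 7.54-fold lower. The probe, a single spot, lies on chromosome 20 from 56942283 to 56942342 in the file's coordinates, whose genome build is not given in the sources used here, and the file does not say which part of the gene it covers. The deposited values of this probe contradict each other. Its raw signal was 383 on the mimic array and 1890 on the control array, 4.94-fold lower before any scaling, whereas its normalized log2 values of 9.74 and 11.13 in the authors' deposited table give a difference of -1.39, or 2.62-fold lower. On the mimic array the normalized value exceeded log2 of the raw signal by 1.16 for RAB22A and by 0.02 to 0.41 for the other 20290 probes. RAB22A was also the only probe of the 1367 marked Down whose raw signal ratio differed from the deposited fold, and a raw mimic signal of 720 would have matched that fold. Which of these values is the measurement is not known. The 7.54-fold figure rests on the raw signal, and the lack of that equality does not show that this signal is unaltered.

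**Figure D2:**
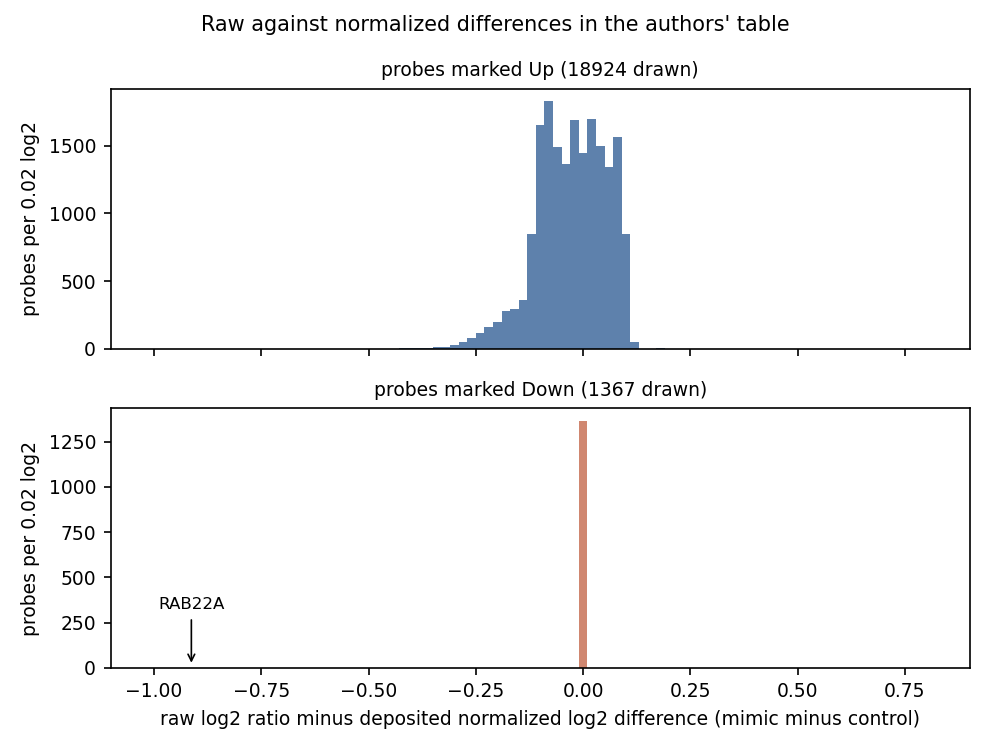
For each probe of the authors' table, the raw log2 ratio of mimic to control minus the deposited normalized log2 difference (horizontal), counted in bins of 0.02 (vertical), with probes marked Up in the upper panel and Down in the lower. The 18924 probes marked Up spread from -0.42 to 0.18 with an SD of 0.081, while 1366 of the 1367 probes marked Down stand at 0 and RAB22A stands at -0.91.

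Among 35 measured genes recalled as reported miR-204-5p targets, 15 were at least 1.5-fold lower on the mimic array and 5 were at least 1.5-fold higher. After RAB22A, large differences were in IL11, a cytokine of the interleukin-6 family (404 against 47347), the transcription factors CREB5 (75.1 against 1151) and SNAI2 (247 against 3286), and the TGF-beta receptor TGFBR2 (3233 against 23580). USP47, RUNX2 and BCL2 were lower by 3.83-fold, 2.86-fold and 2.73-fold, but the pair of RUNX2 probes disagreed in direction (-3.18 and 0.14). EZR, which encodes the membrane linker ezrin, was higher by 7.07-fold, as were PLEKHG5 by 4.22-fold and SOX4 by 2.90-fold. The pair of PLEKHG5 probes differed in size (3.60 and 0.55), as did that of BCL2 (-2.20 and -0.70). The list's median difference was -0.36, at percentile 1.63 among 10000 random lists matched on mean intensity, as a description of these arrays, and it lay inside the central 95% of random lists under 6 of 11 alternative settings. IL11, CREB5, SNAI2, TGFBR2, USP47, RUNX2 and BCL2 each had a recomputed probe, and without the recomputed probes, a choice made after the data were examined that removes lower genes by construction, the median of the remaining 29 members relative to all genes was -0.06 at percentile 35.0.

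Epithelial genes stood furthest from the random lists on the higher side. Of 16 measured members, 13 were at least 1.5-fold higher on the mimic array and 0 were lower by that much, with a median difference of 2.89 at percentile 100. With no detection filter 17 of 20 members were higher and 1 lower. CLDN1, a member outside the authors' table, was 20.6 against 3536. CDH1, the adherens junction protein E-cadherin, was 309-fold higher (11324 against 36.6), and EPCAM, an epithelial adhesion molecule, was 108-fold higher (65569 against 608). The membrane protease gene ST14 was 32.8-fold higher and the tight junction gene CLDN3 was 27.3-fold higher. None of the 11 epithelial genes at least 2-fold higher had a recomputed probe.

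Mesenchymal genes and factors of the epithelial-mesenchymal transition lay on the opposite side, with 11 of 17 measured members at least 1.5-fold lower, 2 higher and a median of -1.17 at percentile 0. VIM, the intermediate filament vimentin, was 128-fold lower (1279 against 163211). The matricellular genes CCN1 and CCN2 were 51.0-fold and 47.1-fold lower, and TGFBI was 41.6-fold lower, all from recomputed probes. Without such probes the median of 11 members relative to all genes was -0.49 in place of -1.12, at percentile 1.70. Fibroblast markers, of which only 5 were measured, had a median of -1.2 at percentile 1.23 but went both ways: the collagen gene COL1A1 was 6.48-fold higher and ACTA2 3.51-fold higher, and PDGFRB and COL1A2, from recomputed probes, were 3.95-fold and 3.49-fold lower. Without the recomputed probes the fibroblast median turned to 1.80 relative to all genes, over 3 members.

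Interferon-response and inflammatory genes were lower on the mimic array. Of 32 measured interferon-response genes, 22 were at least 1.5-fold lower and 0 were higher, with a median of -1.46 at percentile 0. IFI44 had an intensity of 30.6 against 10838, IFIT3 36.6 against 5776, IFIT2 711 against 42693 and OASL 475 against 12521, all from recomputed probes. Of 19 measured NF-kB and cytokine genes, 14 were lower and 2 higher, with a median of -1.45 at percentile 0. The cytokine genes IL1B, IL6 and CXCL8 were 372-fold, 35.4-fold and 30.4-fold lower, again from recomputed probes. Without those probes the medians relative to all genes were -0.36 for 18 interferon-response genes and -0.77 for 12 NF-kB and cytokine genes, in place of -1.41 and -1.4.

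Genes activated by p53 were higher on the mimic array, 18 of 25 measured by at least 1.5-fold and 0 lower, with a median of 1.13 at percentile 100. FDXR, a mitochondrial ferredoxin reductase, was 14.6-fold higher, PHLDA3 was 9.82-fold higher, the antiproliferative gene BTG2 was 8.65-fold higher and TP53INP1 was 5.35-fold higher. The control value of PHLDA3 (42.5) was under 10 times the negative-control median, so the size of its fold depends on the floor. The BCL2 family and apoptosis list was divided, with 11 of 28 genes higher, 7 lower and a median of 0.35 at percentile 97.2, inside the central 95% of random lists. In it the BH3-only gene BIK was 28.6-fold higher, BBC3 4.10-fold higher, CASP6 2.82-fold higher and the inhibitor of apoptosis BIRC3 6.84-fold lower, from a recomputed probe.

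Of 30 genes of G1/S and DNA replication, 15 were at least 1.5-fold higher and 2 lower, with a median of 0.60 at percentile 100. The replication licensing factor CDT1 was 6.19-fold higher, the ribonucleotide reductase subunit RRM2 5.61-fold, cyclin E1 (CCNE1) 5.02-fold and ORC1 4.68-fold. Genes of G2/M and mitosis did not stand apart from random lists (5 of 32 higher, 13 lower, median -0.28, percentile 6.92), although CENPE, DLGAP5 and ASPM were 6.49-fold, 4.57-fold and 4.30-fold lower from recomputed probes and AURKB was 3.65-fold higher. Canonical histone genes had a median of -1.03 at percentile 0.01, with 10 of 15 lower and 2 higher. The linker histone genes H1-4 and H1-2 were 8.17-fold and 6.35-fold lower, H4C8 was 4.70-fold lower, all from recomputed probes, and H3C8 was 2.69-fold higher.

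Several metabolic and signalling lists were higher on the mimic array. Of 26 cholesterol and fatty acid synthesis genes 13 were higher and 3 lower (median 0.60, percentile 99.9), led by the desaturase SCD at 20.2-fold, with MVD at 4.03-fold, SQLE at 3.85-fold and FASN at 2.88-fold. The file's coordinates place the only SCD probe on chromosome 17, and whether it reads SCD itself was not checked. Of 21 genes of the unfolded protein and amino acid stress response 11 were higher and 2 lower (median 0.68, percentile 99.98). The serine synthesis gene PHGDH was 4.88-fold higher, PDIA4 3.75-fold and HSPA5 2.99-fold, while EDEM1 was 3.07-fold lower from a recomputed probe. This list lay at percentile 94.2 when the brightest probe stood for each gene. VLDLR, a member outside the authors' table, went the opposite way (15.0 against 2060). Of 21 listed WNT/beta-catenin targets only 12 were measured, of which 6 were higher and 0 lower (median 0.66, percentile 99.4). The higher genes included BMP4 at 4.79-fold, SOX9 at 3.35-fold, AXIN2 at 2.97-fold and CCND1 at 2.79-fold. LEF1, a member outside the authors' table, went the opposite way (7.02 against 3965). The list lay at percentile 91.3 with no detection filter, 90.7 in the brighter part of the probes and 97.2 with normexp. Oxidative phosphorylation genes had a smaller median of 0.32 at percentile 99.3, with 6 of 31 higher and 1 lower, and NDUFB10, CYC1, SDHB and NDUFS3 between 2.03-fold (NDUFS3) and 2.77-fold (NDUFB10) higher.

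The other lists lay within the central 95% of random lists. RAB GTPases and endosomal trafficking genes had a median of -0.27 (percentile 8.23), with 11 of 30 lower and 4 higher. Besides RAB22A, the endosomal tether EEA1 was 5.35-fold lower, RABGEF1 was 3.08-fold lower, both from recomputed probes, and RAB4A was 4.39-fold higher. Genes of the miRNA pathway had a median of -0.19 (percentile 20.3), with DGCR8 2.55-fold higher and DCP2, AGO3 and DROSHA between 1.83-fold (DROSHA) and 2.16-fold (DCP2) lower. Cytosolic ribosomal protein genes had a median of 0.13 (percentile 95), with 9 of 43 higher and 0 lower, RPL22 at 2.79-fold, RPS3 at 2.34-fold, RPS9 at 2.03-fold and RPL13 at 1.98-fold. In the file's coordinates the RPS3 probe lies on chromosome 6, the RPS9 probes on 19 and 22 and the RPL22 probes on 1 and 3. Whether these probes read the named genes themselves was not checked. Housekeeping genes had a median of 0.05 (percentile 73.9), with 3 of 18 higher and 3 lower, and the sign of that median relative to all genes turned when the brightest probe stood for each gene (-0.15). GUSB was 2.12-fold lower and POLR2A 1.70-fold higher, while EEF1A1 and ACTB were 1.90-fold and 1.60-fold higher as means of probes that disagreed in direction. The file's coordinates place the EEF1A1 probes on chromosomes 1, 2, 6 and 7 and the ACTB probes on 1 and 7. Blood cell markers had a median of -0.34 (percentile 16.6), with CD68 3.90-fold lower from a recomputed probe, CD79A 2.08-fold higher and CD3E and PTPRC within 1.5-fold. Endothelial markers had a median of -0.50 (percentile 21), with ENG 3.44-fold lower from a recomputed probe, EMCN 1.67-fold lower and CDH5 and VWF within 1.5-fold.

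**Figure D3:**
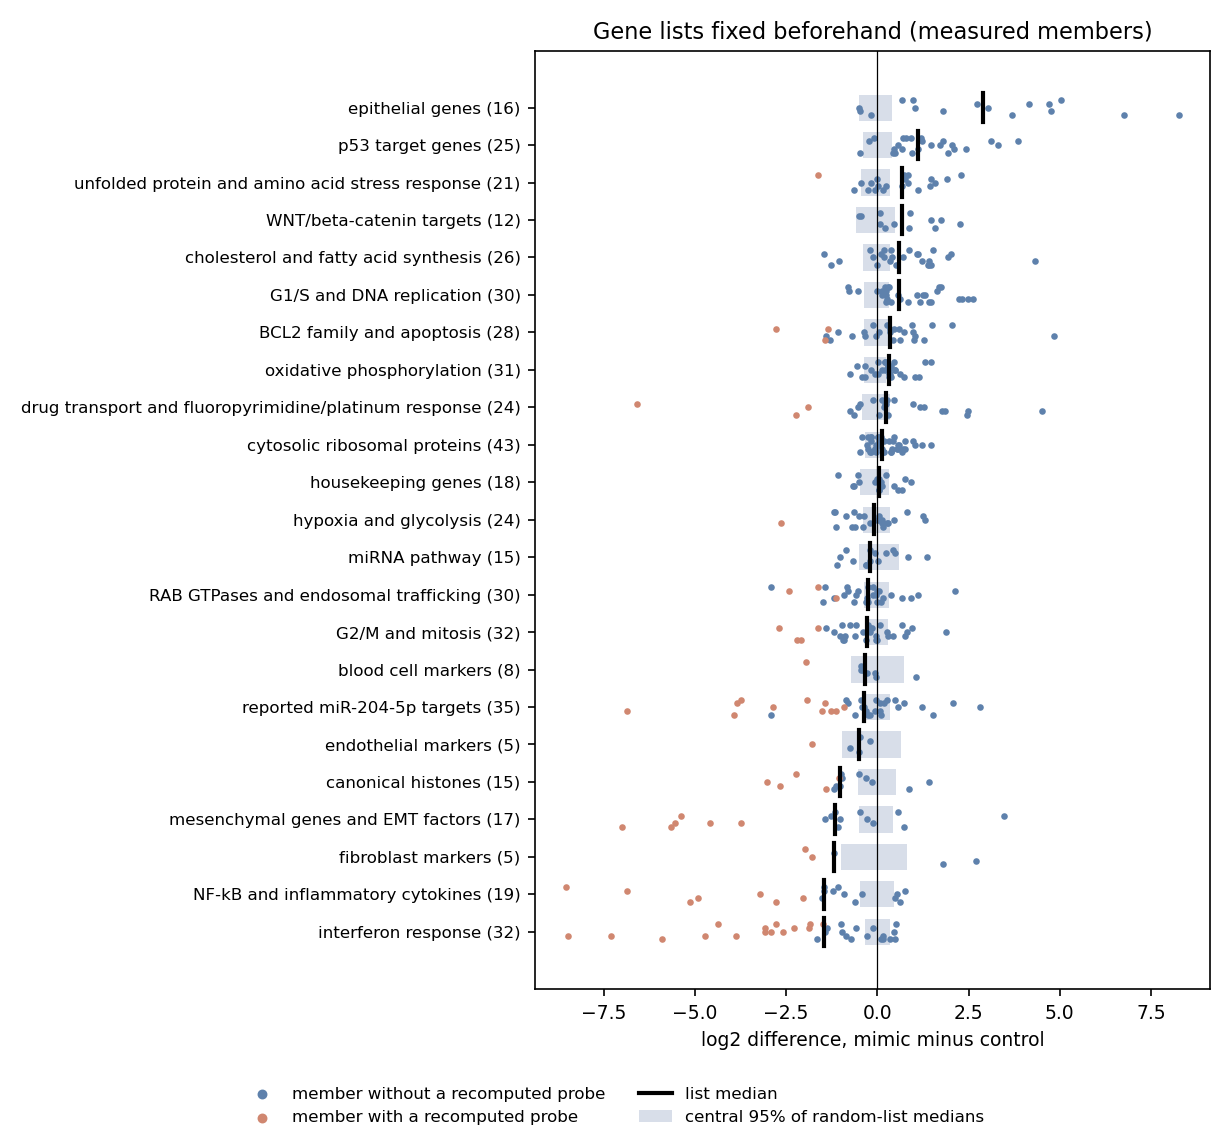
Log2 difference (mimic minus control, horizontal) of each measured member of the gene lists (rows, number measured in parentheses), with orange points for members that have a recomputed probe, a black bar for the list median and a grey band for the central 95% of medians of 10000 random lists. Medians run from -1.46 for the interferon response to 2.89 for epithelial genes.

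The deposited normalized values were set beside the scaling used here. Across 20291 probes, which are not independent replicates, the log2 differences from both sources correlated at r = 0.998, and the deposited difference was higher by a median of 0.62. Both sources start from the same 2 arrays, and at the recomputed probes the raw ratio is the deposited fold, so their agreement was given beforehand. The correlation without those probes was not computed. At probes marked Up the deposited minus own difference had an SD of 0.082. The authors' deposited table marks 18924 probes Up, of which 3346 have a deposited fold below 1, and marks 1367 probes Down, all at least 2-fold lower. The mark Up therefore does not mean a higher value in that table.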

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

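The result in this part was chosen after the data were examined. Outside the authors' table, which the comparisons above rest on, 132 of 13836 probes were over 100 times the negative-control median on the mimic array and under 5 times on the control array, a signal in probes that the gene counts do not use. In the other direction 188 probes were that bright on the control array and that dim on the mimic array. The brightest named genes of the first kind were GTSF1 (84181 against 14.4), EMC10 (27221 against 4.59) and GDA (16693 against 5.59). Those of the second kind were TXNIP (16.4 against 49791), G0S2 (4.80 against 31556) and COX7B2 (4.25 against 25192). The scaled negative-control median was 4.52 on the mimic array and 4.45 on the control array, so no fold is given for these probes.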

How the results depend on the processing

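Alternatives chosen after the data were examined were the deposited values less 0.6, the results without recomputed probes and the scaling on the table's median. Medians and gene values here are relative to the median of all genes, and the cause of a change was not tested unless named. No paired analysis was possible because each group has 1 array. The seed-site comparison, with its alternatives for the 3' UTR and for matching on its length and GC content, and the target list limited to genes with a site were not run. Of the counts at 2-fold, 16 of 26 alternative values were within 1.5 times the main count. Higher genes (main 2082 of 14933) numbered 4616 with the deposited values, 1083 of only 8514 genes in the brighter part of the probes, 3512 at 1.5-fold and 1002 at 3-fold. Lower genes (main 2134) numbered 1022, 1266, 3694 and 1061 in the same order. They numbered 3471 of 20829 genes with no detection filter and 1062 of 13984 without recomputed probes, an alternative that removes probes marked Down by construction. Part of these changes in number therefore comes from the number of genes in a setting. The target median (main -0.31, percentile 1.63) kept its sign in all 11 alternatives but entered the central 95% of random lists in 6: -0.29 by quantile normalization, -0.29 with the deposited values with or without 0.6, -0.27 in the brighter part of the probes, -0.25 with the brightest probe and -0.062 without recomputed probes. RAB22A (main -2.86) was -2.95 by cyclic loess, -1.98 with the deposited values with or without 0.6, -2.64 by normexp, -2.75 with 32 added and -2.93 without recomputed probes. Of 240 other list values, 235 were on the same side of the central 95% of random lists as the main value, but inside it the housekeeping median changed sign with the brightest probe (-0.15) and the hypoxia median with normexp (0.027), no filter (0.055) and the brighter part of the probes (0.084). The WNT median (main 0.72) lost its place with normexp (0.42), with no filter (0.13) and in the brighter part of the probes (0.49), as did the unfolded protein list with the brightest probe (0.31), and the fibroblast median turned to 1.80 without recomputed probes. Of 1200 values of named genes, 400 moved by more than 0.064, the median SD of the spot-wise log2 difference. Of the named genes, ACTB (-0.34) and EEF1A1 (-0.023) reversed with the brightest probe and RUNX2 (0.13) without recomputed probes. Table probes over 10 times the negative-control median made up 94.7% on the mimic array and 97.6% on the control array, but 11 of 116 named genes were under that on 1 array. Their folds depend on the floor, as for CDH1 (main 8.33, 7.42 with 32 added), S100A14 (8.75, 7.92), GNG11 (-10.28, -9.14), MAGEC1 (-8.65, -7.84), IFI44 (-8.41, -7.39), IFIT3 (-7.25, -6.36) and IL1B (-8.48, -7.29). The others were PHLDA3, COL1A2, ENG and EMCN.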

Other observations

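The gene lists of this paragraph were fixed before the data were examined, and the tests of explanations that follow were chosen afterwards, except that the outcome of the test of neighbouring genes was predicted before it was run. Among 24 measured genes of drug transport and of the fluoropyrimidine and platinum response, 8 were at least 1.5-fold higher on the mimic array and 5 lower, with a median of 0.23 at percentile 90.9. DPYD, the enzyme that degrades fluorouracil, was 97.1-fold lower (85.6 against 8317), from a recomputed probe. The transporter genes ABCC2 and ABCC1 were 22.8-fold and 5.47-fold higher. Hypoxia and glycolysis genes had a median of -0.10 at percentile 35.3, with 3 of 24 higher and 8 lower. SLC2A3, a glucose transporter, was 6.21-fold lower from a recomputed probe and BNIP3 2.29-fold lower, while NDRG1 and P4HA1 were 2.48-fold and 2.38-fold higher, and the sign of the list's median relative to all genes turned under 3 alternatives.

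The first pattern is in the raw mimic signals of the probes marked Down. A raw signal computed from the control signal and the deposited fold is a candidate explanation, since 1366 of 1367 such probes had a raw ratio equal to the fold, RAB22A being the exception, against 0 of 18924 others. Spots copied from the control array by 1 factor per probe are argued against by the correlation of spot deviations between the arrays, 0.27 over 705 spots of Down probes and 0.37 over 6951 spots of Up probes. No biological explanation was tested, and how the values arose, including the different treatment of RAB22A, stays open. At 7 Down probes some mimic spots were on the 1.2 pattern of the other spots (9 of 10 at ZNF586, RND3, HPS3 and IL6, 1 of 10 at GSTA4, GSTM1 and ZNF485). A single spot on it can be a match by coincidence, so only the first 4 probes give a second reading. There the deposited log2 fold minus the raw log2 ratio of the spots on the pattern lay between -0.11 and 0.0076. At the other recomputed probes the size of the difference was not checked. Of the 2134 lower genes, 995 have no recomputed probe, but the mark Down, cut at -1, sets that split. Without recomputed probes 35 genes were at least 3-fold lower, against 1061 with them.

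The second pattern is that deposited normalized values were higher on the mimic array. A constant of 0.6 added to the mimic column may account for it, since 90.84% of Up probes fell on a control value after that shift and at most 0.98% at any other, although rank by rank 12.5% of the 1000 highest values lay 0.6 apart within 2e-06, a comparison in which the Down probes change the ranks. Higher transcript levels in mimic-transfected cells were not tested, since a shared set of values says nothing about the level of a gene. A constant missing from the Down probes as a whole would make the folds of recomputed probes given here too large by a factor of 1.53. It is argued against by 624 probes with a deposited difference from -1.6 to -1.0 and 1423 from -1.0 to -0.4. A mark set by a cut at -1 before or after the shift would leave 1 of these stretches empty. The 4 probes with 9 of 10 spots as a second reading, all within 0.11, also argue against it. How the normalized values of single Down probes arose stays open, since at most 1.54% of them fell on a control value at any shift.

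For the third pattern, higher epithelial genes with lower mesenchymal, interferon and NF-kB genes, recomputed values are argued against for the epithelial genes, 0 of 11 of which had such a probe. Of the others, 28 of 41 members at least 2-fold lower had one. A second reading from spots of the same probe was at hand for IL6 alone, so the size of these falls stays open. The lower direction did not rest on recomputed probes alone in the mesenchymal and interferon-response lists. Without them the medians relative to all genes were still low, -0.49 (percentile 1.70) and -0.36 (percentile 1.82). Fibroblasts as the whole cause, which would have to make up most of the control culture, are argued against by the abundant collagen COL1A1, which differed by 2.70 log2 towards the mimic array, with COL3A1 at 18.9 against 20.8. Probes of other markers outside the table went the opposite way (DCN 5.32 against 33.3, FAP 4.40 against 42.8, THY1 13.2 against 44.4), and with no detection filter 8 of 12 were at least 1.5-fold lower on the mimic array and 2 higher, so a smaller share stays open. It is a hypothesis that the arrays, both labelled HCT116, hold different cell lines, which differ in chromosome copy number: differences of genes 50 places apart along the autosomes had a rank correlation of 0.0664 (0.0689 without recomputed probes), above the highest of 1000 shuffles, 0.0288. Neighbouring genes on chromosome 9, chosen after their values were seen, were bright on the mimic array and dim on the control array (FOCAD 7696 against 8.2, KLHL9 4298 against 28, MTAP 974 against 4.13 and 664 against 4.15). So were MIR31HG (300 against 5.83) and a CDKN2A probe outside the table (2640 against 12.65). The table's probe of CDKN2A (27948 against 646) had clear signal on the control array, and that of MTAP (8551 against 43.5) had weak signal there. CDKN2A-AS1 (56.0 against 70.8) was weak on both arrays, and other neighbours, such as HACD4 and CDKN2B, were near the floor on both. A segment lost from the control cells therefore stays open. Regional base composition or regulation could also give the correlation, and regulation could also give the chromosome 9 values. An effect of the mimic on these genes stays untested with 1 culture per group.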
